A study of Homo sapiens with 6 samples.

How the data were processed

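Total RNA of A673 and SK-N-MC cells was amplified, labelled with biotin and hybridised to Affymetrix whole-transcript arrays, 1 array per cell line and siRNA, 6 in all. The submitters' processing notes name Affymetrix Expression Console and RMA, a method that corrects background, normalizes between arrays and summarises the probes of a probe set. The software version, the settings and the genome build are not given in the sources used here, and so no coordinates are printed. The deposited values are taken as log2 RMA values per probe set, a scale read from their range of 1.02 to 13.4 and not stated in the labels. RMA makes the arrays' distributions alike and compresses differences of dim probe sets, so folds near the floor understate the change. No scanner files were used here, so signal over background could not be measured.

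The table held 33297 probe sets and 6 columns, each matched to 1 sample by its label, with 0 columns used by no sample. Gene names came from a table of the platform's annotation, which can be old, updated through Entrez gene numbers. Of the probe sets 19460 had 1 symbol, 1754 had several and 12083 were not listed there; 19429 Entrez numbers matched the current gene table and 0 symbols changed. Probe sets with several symbols or none were not named. For the 769 genes with several probe sets, the probe set with the highest mean over all arrays was kept, which left 18417 genes. Of the genes in the fixed lists, 31 were not analysed here.

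The main tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on all 6 arrays with siRNA and cell line as terms, so that the 3 siRNA groups shared 1 estimate of the spread. The lines pair the arrays across siRNAs, per the labels, and the fit kept the line as a block. It left 2 residual degrees of freedom, moderated to 8.28 with a prior of 6.28. The cell line comparison used the same fit with siRNA as the block. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. The 4 comparisons were siDKK2 against control, siITM2A against control, siDKK2 against siITM2A, and A673 against SK-N-MC. Nothing in the labels says that arrays came from repeat cultures of 1 condition, so the p-values measure only how evenly the 2 lines responded. With 1 array per line and siRNA there is no test within a line or of a difference in response between lines. Beside the tests, genes were counted that differed at least 2-fold in the same direction in both lines.

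The 28 gene lists were written before the data were examined, from general knowledge of Ewing sarcoma, Wnt and DKK signalling, bone, invasion, siRNA transfection responses and other cell types; 1 of them, the genes of interest to the study, came from knowledge of work on these cells. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 28 lists of a comparison. An estimated correlation and limma's fry, which asks whether a list's genes moved on balance in 1 direction, were the alternatives. Camera with an estimated correlation rests on the 2 residual degrees of freedom. It called 0 lists in each comparison, so the loss of a call under it does not tell lists apart. A list's median was also set beside the medians of 10000 random lists matched on level. The random lists drew genes independently, so they do not reflect lists whose members vary together. Correlations of differences that share a control array were set beside 100 simulations of unchanged groups.

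Genes were named by a rule fixed before the data were examined: DKK2 and ITM2A; per comparison the 10 higher and 10 lower genes with the largest smaller-of-the-lines difference among those past the threshold, with open places filled by genes that did not pass and given as values only, all at or above the median level of 4.04; up to 4 members of each list by the same order; and every member of the study's list. Other genes named are said to have been chosen after their values were seen. The design, the tests of the 4 comparisons and the alternatives were also fixed before the data were examined, apart from 2 alternatives, and apart from the tests of explanations that the closing section names as chosen after the results were seen.

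The fit was tested on simulated data for siDKK2 against control, with 200 of 18417 genes changed in each of 10 runs. With variances drawn from the fitted prior it recovered 3.6% of genes changed by 0.5 on the log2 scale, 80.4% at 1, 99.4% at 2 and 100% at 4, with 4.84% false calls among all calls. A first simulation, which gave each gene its own moderated variance as the true one, had 10.3% false calls and recovered 28.2% at 0.5; the prior draw was adopted after that result was seen, because it matches the model eBayes assumes. Both simulations found 10 of 10 lists of 20 genes shifted by 0.5 and 0 of 10 lists left unshifted. Noise was drawn independently for each gene, so the members of these lists did not vary together. The result therefore does not cover lists such as the interferon list, with an estimated correlation of 0.945. Neither simulation let the lines respond differently, as the interferon genes did. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

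The alternatives were a fit without the block, a filter at the median level, an intensity trend or robust moderation in eBayes, quantile normalization or median centring of the deposited values, every probe set with a gene name in place of 1 per gene, the 4 arrays of a comparison alone, and leaving out each array in turn. Leaving out an array leaves a siRNA with 1 array, which is then assumed to vary like the others. In that fit the difference leans on the other siRNAs' line difference, so a gene whose line difference depends on the siRNA can shift. Leaving out either array of the siRNA outside a comparison gives the same fit as the 4 arrays alone, so these are not separate checks.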

Results

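Gene expression was measured on 6 Affymetrix arrays, 1 for each combination of 2 cell lines and 3 siRNAs. A673 and SK-N-MC are established lines of Ewing sarcoma, a tumour of bone and soft tissue driven by a fusion of EWSR1 with an ETS transcription factor gene. Each line received a control siRNA that silences no gene, an siRNA against DKK2 (siDKK2), or an siRNA against ITM2A (siITM2A). DKK2 encodes a secreted modulator of Wnt signalling of the Dickkopf family, and ITM2A encodes a membrane protein that the design used as a second, separate knock-down. The comparisons ask which transcripts changed when DKK2, a gene the series title ties to bone destruction, invasion and metastasis, was silenced. The arrays were even in overall level, with medians of 3.35 to 3.44 over 33297 probe sets on the log2 scale. Arrays of the same line correlated at 0.986 to 0.991 across probe sets and arrays of different lines at 0.959 to 0.965. There was 1 array per line and siRNA, so the 2 lines were the replicates of each siRNA effect, and their number limits the precision.

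Each target gene had its lowest value with its own siRNA in both lines. DKK2 (probe set 8102200) stood at 8.64 on the log2 scale in A673 control cells and 7.73 with siDKK2, and at 8.01 and 6.50 in SK-N-MC, which left 53% and 35.1% of the control level. ITM2A (probe set 8173755) stood at 8.52 in A673 control cells and 5.03 with siITM2A, and at 9.48 and 6.10 in SK-N-MC, which left 8.86% and 9.55%. The fitted difference of DKK2 with siDKK2 was -1.21 ± 0.17 (SE, n = 2 lines). It missed the threshold over all genes (limma, adjusted p = 0.209) and passed it when adjusted over the list alone (adjusted p = 0.00171 among 20 genes of interest to the study, a list drawn from knowledge of work on these cells and so not independent evidence). With an intensity trend in the moderation DKK2 passed over all genes (adjusted p = 0.0254, the lowest over its alternatives, the highest being 1.00 without the line term). ITM2A fell by 3.44 ± 0.17 with siITM2A (adjusted p = 0.000442). Neither siRNA lowered the other target past the threshold: ITM2A differed by 0.43 ± 0.17 with siDKK2 (adjusted p = 0.537) and DKK2 by 0.20 ± 0.17 with siITM2A (adjusted p = 0.874). The labels number the ITM2A siRNA 7 in A673 and in the design text but 1 in SK-N-MC, so whether both lines received the same oligonucleotide stays open.

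**Figure D1:**
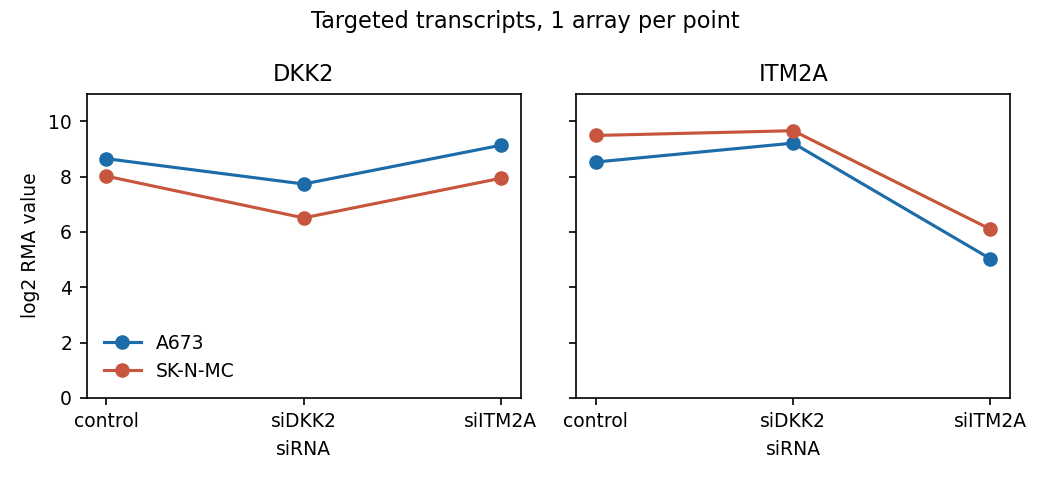
Log2 RMA values of DKK2 and ITM2A by siRNA in A673 and SK-N-MC, 1 array per point, with lines joining the arrays of a cell line. DKK2 lies lowest with siDKK2 (7.73 and 6.50) and ITM2A lowest with siITM2A (5.03 and 6.10).

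With siDKK2 the leading difference from the control siRNA was lower expression of interferon-induced genes, and it was larger in A673 than in SK-N-MC. Across the 23 measured members of the interferon-response list the median difference was -3.07 in A673 and -0.79 in SK-N-MC, and 20 of 23 were lower in both lines. IFIT1, an interferon-induced binder of foreign RNA, was 26.1-fold lower in A673 and 3.87-fold lower in SK-N-MC. The oligoadenylate synthetase OAS1, which makes the activator of RNase L, was 24.7-fold and 3.16-fold lower, IFI44L 26.3-fold and 3.07-fold, and the cytosolic RNA sensor RIGI 7.01-fold and 2.23-fold. IRF9, the DNA-binding part of the interferon-stimulated factor ISGF3, differed by -1.93 and -1.29. The median level of the list was 6.40 in A673 control cells, 3.41 with siDKK2 and 5.37 with siITM2A, against 4.28, 3.24 and 3.77 in SK-N-MC. With siDKK2 both lines thus ended near the medians of those arrays, 3.35 in A673 and 3.39 in SK-N-MC, and background was not measured. SK-N-MC started lower, so its folds may be limited by the floor, and a weaker response cannot be told apart from that.

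The interferon list was lower by limma's camera with a preset correlation (median -1.70 over both lines, adjusted p = 1.0e-25), a call that was lost at adjusted p = 0.898 with an estimated correlation. The member genes varied together, with an estimated correlation of 0.945, far above the preset 0.01, so the preset p-value overstates the evidence. The loss was not particular to this list. Immediate early genes between the lines, at an estimated correlation of -0.02, lost their call as well (camera, adjusted p = 0.626). Limma's fry called the immediate early list between the lines (fry, adjusted p = 0.0251) but not the interferon list with siDKK2 (fry, adjusted p = 0.619). Over all genes 0 of the 23 passed the threshold (limma, 22 at an unadjusted p under 0.05), while 22 passed when adjusted over the list alone. The closest was IRF9, at -1.61 ± 0.17 (adjusted p = 0.0566). It stood at -1.83 without the SK-N-MC control array and -1.86 without the SK-N-MC siDKK2 array. Without the same arrays IFIT1 stood at -4.13 and -4.59, OAS1 at -3.99 and -4.52 and RIGI at -2.44 and -2.77. Those fits leave out an array of the line with the smaller difference and lean on A673, so they add no replication. Without the A673 control array the list's median was -1.22. The difference in size between the lines was not tested, since each line had 1 array per siRNA. Leaving out any 1 of the 6 arrays kept the camera call, and the median was -2.72 without the SK-N-MC siDKK2 array, -2.68 without the SK-N-MC control array and -0.85 without the A673 siDKK2 array.

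**Figure D2:**
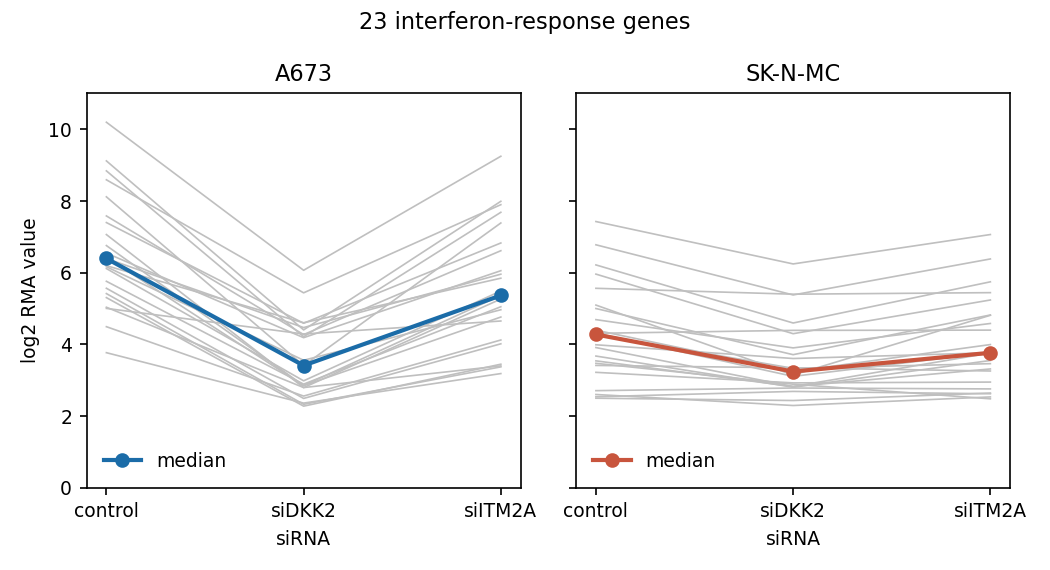
Log2 RMA values of the 23 measured interferon-response genes by siRNA, with A673 in the left panel and SK-N-MC in the right; grey lines are genes and the coloured line is their median. The medians are 6.40, 3.41 and 5.37 in A673 and 4.28, 3.24 and 3.77 in SK-N-MC for control, siDKK2 and siITM2A.

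Over all genes, 2 changed with siDKK2, both lower and neither in the interferon list. ANKRD46 (probe set 8152053), which encodes an ankyrin-repeat protein, fell by 1.87 ± 0.13 (adjusted p = 0.00467; -1.77 in A673 and -1.98 in SK-N-MC). ATP6V1D (probe set 7979698), a subunit of the vacuolar proton pump, fell by 1.78 ± 0.13 (adjusted p = 0.00467; -1.81 and -1.76). No gene passed in the upward direction. The genes with the largest smaller-of-the-lines higher values, none past the threshold, were SSU72 (0.83 ± 0.14), GXYLT2 (0.74 ± 0.13), PCDH7 (0.68 ± 0.13) and NPW (0.67 ± 0.18). IGKC, PRSS35, C8orf82, CA11, SMIM15 and IGFBP2 followed at 0.63 to 0.98. PRSS35 stood at 1.15 without the SK-N-MC control array.

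By size alone, 13 genes were at least 2-fold lower with siDKK2 in both lines and 0 were at least 2-fold higher, where 0.269 lower genes would be met if the lines were independent. Among the 13 were members of the interferon list, IFIT1, OAS1, IFI44L, IFI44, IRF9, OAS3, IFI6, RIGI and the chemokine gene CXCL10. The rest were ANKRD46, ATP6V1D, the methyltransferase gene CARNMT1 (-1.06 and -1.52) and the double-stranded RNA kinase gene EIF2AK2 (-1.50 ± 0.23); CARNMT1, EIF2AK2 and CXCL10 were named after their values were seen. At 1.5-fold the counts were 77 lower and 11 higher in both lines, with 15 in opposite directions.

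Core histone genes were higher with siDKK2 by camera (12 measured, median 0.17; 0.36 in A673 and 0.02 in SK-N-MC; adjusted p = 0.0111, and adjusted p = 0.898 with an estimated correlation). H3C1 was the most shifted member, at 1.00 in A673 and 0.27 in SK-N-MC, and no member passed over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05). Genes of cholesterol synthesis and uptake were lower (15 measured, median -0.18; adjusted p = 0.0262, and adjusted p = 0.898 with an estimated correlation), with 9 of 15 lower in both lines. Of 10000 level-matched random lists 9.73% had a lower median than the cholesterol list in A673 and 7.15% in SK-N-MC, and 69.15% a lower one than the histone list in SK-N-MC, against 100% in A673. STARD4, a sterol carrier, differed by -1.86 and -0.91 and was the 1 member that passed when adjusted over the list alone; 0 passed over all genes (limma, 4 at an unadjusted p under 0.05). STARD4 stood at -1.74 without the SK-N-MC control array and at -1.74 without the SK-N-MC siDKK2 array, fits that lean on A673. The histone call was lost without the A673 control array (median 0.07) or the A673 siDKK2 array (0.08), and its median was 0.28 without the SK-N-MC control array and 0.34 without the SK-N-MC siDKK2 array. The cholesterol call was lost without the SK-N-MC control array (median -0.09) or the A673 siDKK2 array (-0.13).

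Among the genes of interest to the study, the chemokine receptor CXCR4 differed by 0.46 in A673 and 0.64 in SK-N-MC with siDKK2, and the Notch ligand JAG1 by 0.19 and 0.47. The collagenase gene MMP1 stood at 11.59 in A673 control cells and 11.02 with siDKK2, and near 3 in every SK-N-MC array (2.95 to 3.05). IL6 was lower in A673 alone by value (-1.05), and its fitted difference was -0.52 ± 0.25. RUNX2 (-0.17 ± 0.14), ATF4 (-0.11 ± 0.13), HIF1A (-0.19 ± 0.16), TGFB1 (0.10 ± 0.13), SPP1 (0.01 ± 0.13), CTNNB1 (-0.22 ± 0.13) and LEF1 (-0.28 ± 0.17) did not pass either. Of the 20 measured members 0 passed over all genes and 1, DKK2 itself, passed when adjusted over the list alone (limma, 5 at an unadjusted p under 0.05). The 25 lists without a call had medians of -0.19 to 0.07 and a lowest adjusted p of 0.0566. For the Wnt target list the median of 0.02 and the mean of -0.06 differ in sign (camera direction down, adjusted p = 0.934).

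In all, siDKK2 against control gave 2 genes at an adjusted p under 0.05 out of 18417 tested (limma, cell line as a block) and 1598 at an unadjusted p under 0.05, where chance gives 920.85. Both calls were lost (0 genes) without the A673 siDKK2 array (1114 at an unadjusted p under 0.05) or without either siITM2A array (1433), the adjusted p of ANKRD46 and ATP6V1D then lying between 0.0570 and 0.0801. The count was 45 without the SK-N-MC control array and 60 without the SK-N-MC siDKK2 array.

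With siITM2A, 2 genes changed against the control siRNA, both lower. ITM2A itself fell by 3.44 ± 0.17 (-3.50 in A673 and -3.39 in SK-N-MC). BTG3 (probe set 8069565), of the antiproliferative BTG/TOB family, fell by 1.82 ± 0.13 (adjusted p = 0.0049; -1.78 and -1.87). Higher values that did not pass were led by GNPNAT1, an enzyme of amino sugar synthesis, at 1.04 ± 0.14 (adjusted p = 0.303), with SYT11, SPATA20, FERMT2, SMIM15, PGF, VPS4B, H2BC9, NQO1 and ATP1B1 at 0.73 to 1.00. Lower values that did not pass included the protocadherin genes PCDHB16 (-0.88 ± 0.17) and PCDHB5 (-0.87 ± 0.13), MAEA (-0.93 ± 0.14) and SAMD9 (-0.99 ± 0.42).

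Cholesterol genes were lower with siITM2A (median -0.20; -0.14 in A673 and -0.22 in SK-N-MC; camera adjusted p = 0.00066, and adjusted p = 0.892 with an estimated correlation). Of 10000 level-matched random lists 5.1% had a lower median in A673 and 2.27% in SK-N-MC. The siDKK2 and siITM2A differences use the same control arrays, so the lower cholesterol genes with each are not separate results. Between siDKK2 and siITM2A the cholesterol list was not called (median 0.07, camera adjusted p = 0.561). INSIG1, which retains the sterol-sensing SREBP complex, differed by -0.93 and -0.83, STARD4 by -1.07 and -0.61, MSMO1 by -0.47 and -0.39, and mevalonate kinase MVK by -0.34 and -0.67. These 4 passed when adjusted over the list alone and 0 of 15 over all genes (limma, 4 at an unadjusted p under 0.05). Interferon-response genes were lower as well, by a median of -0.95 in A673 and -0.22 in SK-N-MC (adjusted p = 5.3e-05, and adjusted p = 0.892 with an estimated correlation). The SK-N-MC median lay inside the range of level-matched random lists (lowest -0.29) and the A673 median below it (lowest -0.30). MX1 differed by -1.67 and -0.99 and OAS1 by -1.16 and -0.72, and 0 of 23 members passed over all genes or adjusted over the list alone (limma, 2 at an unadjusted p under 0.05). Genes of the amino acid and endoplasmic reticulum stress response were higher (19 measured, median 0.06; 0.09 in A673 and 0.12 in SK-N-MC; adjusted p = 0.0103, and adjusted p = 0.892 with an estimated correlation), above 95.74% of the random lists in A673 and 99.13% in SK-N-MC. DDIT4 (0.72 and 0.60) passed when adjusted over the list alone and 0 members over all genes (limma, 3 at an unadjusted p under 0.05).

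Without the A673 control array the interferon median with siITM2A turned to 0.13 and the call was lost, and without the SK-N-MC siITM2A array it was -0.28, also without a call; without the SK-N-MC control array it was -1.39. The cholesterol call was lost without the SK-N-MC siITM2A array (-0.13). The stress-response call was lost without the A673 siITM2A array (0.11) or the SK-N-MC control array (0.03), and its median was 0.14 without the A673 control array and 0.19 without the SK-N-MC siITM2A array.

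Of the study's genes, JAG1 differed by 0.53 in A673 and 0.54 in SK-N-MC with siITM2A and, with ITM2A, passed when adjusted over the list alone (2 of 20, against 1 over all genes). The list's median of 0.04 and its mean of -0.11 differ in sign (camera direction up, adjusted p = 0.379), the mean including ITM2A itself. The 25 lists without a call had medians of -0.18 to 0.08. By size, 2 genes were at least 2-fold lower in both lines and 0 higher, and at 1.5-fold 31 were lower and 16 higher. The count of 2 changed genes (limma, 1273 at an unadjusted p under 0.05) became 0 without the A673 siITM2A array (957) or the SK-N-MC siITM2A array (902), and 4 without the SK-N-MC control array.

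**Figure D3:**
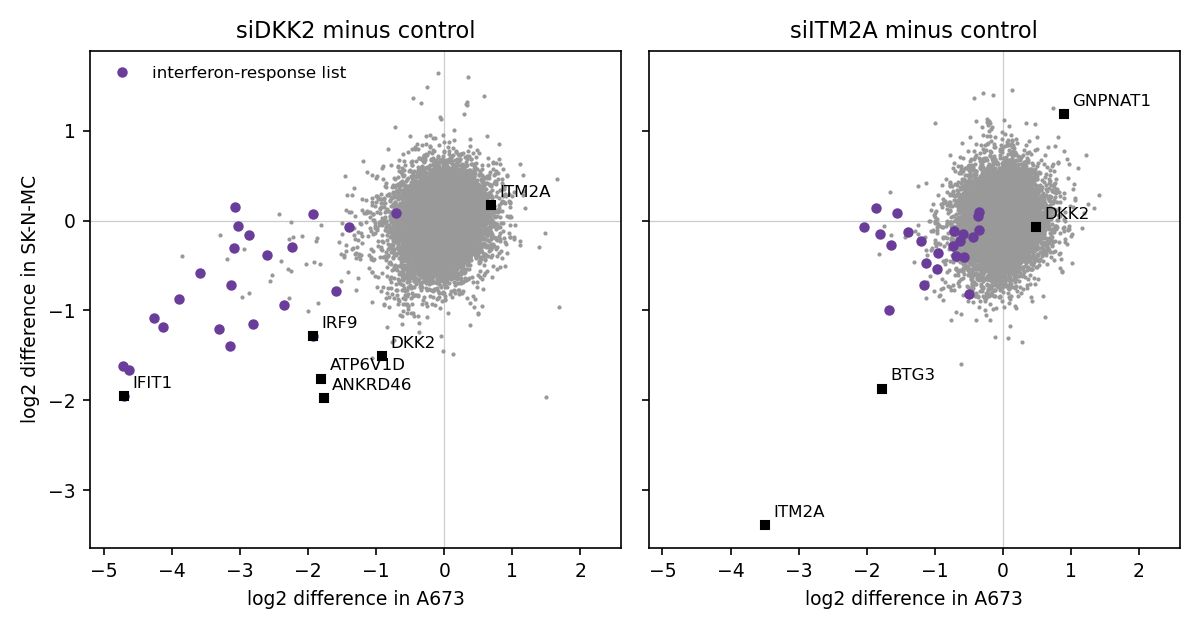
Log2 difference from the control siRNA in A673 (horizontal) and in SK-N-MC (vertical) for siDKK2 (left) and siITM2A (right); each grey point is 1 of 18417 genes, purple points are the interferon-response list and black squares are named genes. ANKRD46 lies at -1.77 and -1.98 with siDKK2, and ITM2A at -3.50 and -3.39 with siITM2A.

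The fitted difference between siDKK2 and siITM2A does not use the values of the control arrays and shows what set the 2 knock-downs apart. Its SE and adjusted p do use them, through the shared estimate of the spread. ITM2A was higher with siDKK2 by 3.87 ± 0.17 (adjusted p = 0.00017), and ANKRD46 and ATP6V1D were lower, at -1.88 ± 0.13 (adjusted p = 0.00376) and -1.54 ± 0.13 (adjusted p = 0.00979). DKK2 differed by -1.40 in A673 and -1.43 in SK-N-MC and missed the threshold (-1.42 ± 0.17, adjusted p = 0.0957), as did TMEM87B (-1.18 ± 0.14) and the integrin-activating adaptor FERMT2 (-1.06 ± 0.13) at the same adjusted p. BTG3 (1.00 ± 0.13), MAEA (1.02 ± 0.14) and PCDHB5 (0.93 ± 0.13) had higher values with siDKK2 without passing. With siITM2A against control FERMT2 was higher, and BTG3, MAEA and PCDHB5 were lower, so these differences do not rest on siDKK2 alone. Leaving out either control array gives the same fit as the 4 siDKK2 and siITM2A arrays alone, with 1 residual degree of freedom. In that fit (limma) DKK2 (adjusted p = 0.0077), TMEM87B and IRF9 (0.0251), FERMT2 and MMP9 (0.0473) and BTG3, MAEA, GLB1L2 and IFIT1 (0.0481) passed. Leaving out the SK-N-MC siDKK2 array makes the siDKK2 estimate rest on its A673 array. There IFIT1 stood at -4.09, IFI44L at -3.75, IFI44 at -2.53, IRF9 at -1.55 and the adhesion gene ICAM1 at -1.76.

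Interferon-response genes were lower with siDKK2 than with siITM2A, by a median of -1.91 in A673 and -0.49 in SK-N-MC (camera adjusted p = 4.2e-16, and adjusted p = 0.723 with an estimated correlation). IFIT1 differed by -3.98 and -1.67 and IRF9 by -1.49 and -1.11; 13 of 23 members passed when adjusted over the list alone and 0 over all genes (limma, 13 at an unadjusted p under 0.05). Genes of the amino acid and endoplasmic reticulum stress response were lower (median -0.16; -0.25 in A673 and -0.07 in SK-N-MC; adjusted p = 0.00296, and adjusted p = 0.723 with an estimated correlation), with 11 of 19 lower in both lines. Of 10000 level-matched random lists 0.06% had a lower median in A673 and 10.24% in SK-N-MC. CHAC1, a glutathione-degrading enzyme of that response, differed by -0.84 and -0.55 and was the 1 member to pass when adjusted over the list alone. Genes of matrix proteases and invasion were lower (26 measured, median -0.14; -0.13 in A673 and -0.14 in SK-N-MC; adjusted p = 0.00663, and adjusted p = 0.723 with an estimated correlation), with 13 of 26 lower in both lines. Random lists with a lower median made up 1.57% in A673 and 0.5% in SK-N-MC. The gelatinase gene MMP9 differed by -1.13 and -0.98, PLAU by -0.52 and -0.28, and the inhibitor gene TIMP2 by -0.31 and -0.26. None passed over all genes or adjusted over the list alone (0 of 26, limma, 5 at an unadjusted p under 0.05). Against control the protease list was not called with siDKK2 (median -0.10, camera adjusted p = 0.575) or with siITM2A (0.05, camera adjusted p = 0.126). The stress-response list was called upward with siITM2A (0.06, camera adjusted p = 0.0103) and not called with siDKK2 (-0.12, camera adjusted p = 0.806). The lower protease and stress-response values here therefore do not show a fall with siDKK2 alone.

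By size, 9 genes were at least 2-fold lower and 1 higher with siDKK2 in both lines. The stress-response and protease calls were both lost without the A673 siDKK2 array (medians -0.04 and -0.11) and without the A673 siITM2A array (-0.11 and -0.17), and the protease call also without the SK-N-MC siITM2A array (-0.17). The stress-response median was -0.29 without the SK-N-MC siDKK2 array and -0.28 without the SK-N-MC siITM2A array, and the interferon median was -2.08 without the SK-N-MC siDKK2 array and -0.39 without the A673 siDKK2 array. The count of 3 changed genes (limma, 1533 at an unadjusted p under 0.05) was 18 without either control array, 50 without the SK-N-MC siDKK2 array, and 1 without either siITM2A array.

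Across 18417 genes, the siDKK2 differences from control correlated between A673 and SK-N-MC at r = 0.186 (Spearman's rho = 0.138), and at 0.156 without the interferon list. The last value still includes interferon-induced genes outside that list. For siITM2A r was 0.097 (rho = 0.0628). Differences of different siRNAs in different lines, which share no array, correlated at 0.0234 and 0.0541, against 0.00184 in simulated unchanged groups. Genes are not independent replicates, so these values describe the arrays. Within a line siDKK2 and siITM2A share the control array, and their differences correlated at 0.512 in A673 and 0.479 in SK-N-MC, where simulated unchanged groups gave 0.499. The covariances were 0.0416 and 0.0301 against 0.023 in the simulation. The single control array of a line could not be split, so the shared control stays in these values.

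The cell lines differed far more than the siRNAs. The collagenase gene MMP1 (probe set 7951271) was higher in A673 by 8.44 ± 0.14 (SE, n = 3 arrays per line), and CCND2, which encodes cyclin D2, was lower by a log2 difference of -5.77 ± 0.12. MMP1 stood at 2.95 to 3.05 in SK-N-MC, below the median of every array, so its difference is a value against a dim probe set whose background was not measured. The same holds for IL1A, at 1.76 to 2.15 in SK-N-MC. Also higher in A673 were the aldo-keto reductase gene AKR1C3 (7.58 ± 0.23), the histone genes H3C11 (6.52 ± 0.16) and H2BC14 (5.36 ± 0.13), CSRP1, SERPINB7, TPTE2, GNG12, the cytokine gene IL1A (5.41 ± 0.15) and the ERK phosphatase gene DUSP6 (5.38 ± 0.18). Lower in A673 were the transcription factor gene TFAP2B (-5.37 ± 0.20), the opioid precursor PENK (-5.30 ± 0.25), the alkaline phosphatase ALPL (-4.20 ± 0.11), ALDH1A1, CMBL, the cell-cycle inhibitor gene CDKN2A (-3.94 ± 0.11), LSAMP, GALNT17 and ELAPOR2. In total 5256 of 18417 genes differed, 2549 higher and 2707 lower in A673 (limma, siRNA as a block), of which 884 and 595 differed at least 2-fold.

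**Figure D4:**
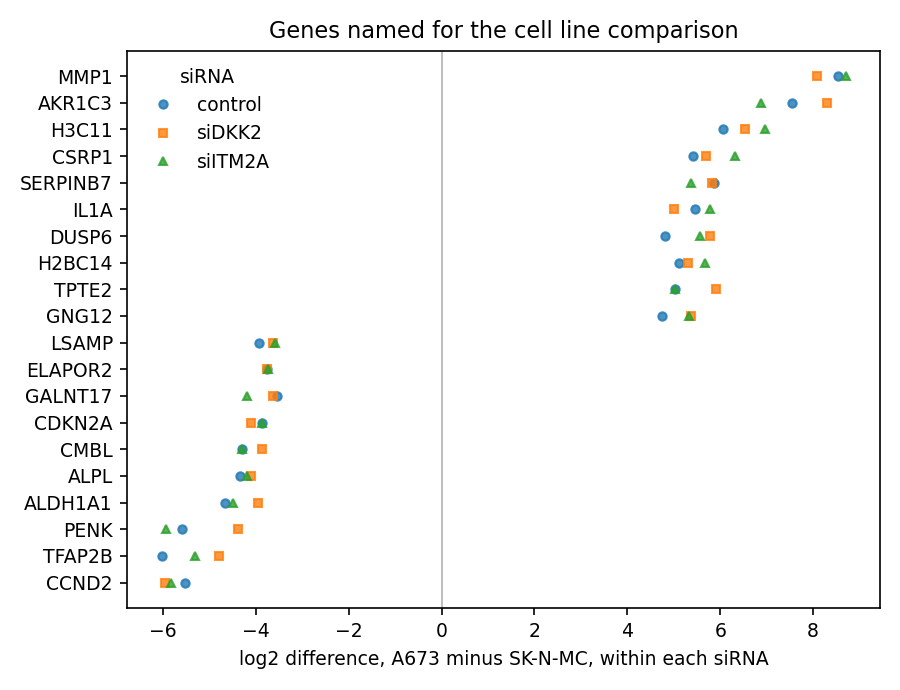
Log2 difference between A673 and SK-N-MC within each siRNA (circles control, squares siDKK2, triangles siITM2A) for the 20 genes named by rule in the line comparison. MMP1 is at 8.07 to 8.70 and CCND2 at -5.95 to -5.53.

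By camera 10 of 28 lists differed between the lines, 8 higher and 2 lower in A673, and 0 with an estimated correlation (lowest adjusted p = 0.626 with an estimated correlation). Limma's fry called 12, of which 8 are among the 10; it did not call the interferon list (adjusted p = 0.211) or the bone resorption list (adjusted p = 0.0949). Matrix protease genes were higher in A673 (median 0.49; 14 of 26 members passed upward and 1 downward over all genes, 15 and 1 adjusted over the list alone; adjusted p = 0.626 with an estimated correlation), among them MMP3 (3.84 ± 0.14) and PLAU (3.23 ± 0.13). Immediate early genes were higher (median 1.25, adjusted p = 0.626 with an estimated correlation), where 12 of 19 passed upward and 1 downward, 13 and 1 adjusted over the list alone, with EGR1 at 3.13 ± 0.14. Chemokine and inflammation genes were higher (median 0.70, adjusted p = 0.653 with an estimated correlation), where 10 of 20 passed upward and 1 downward, 11 and 1 adjusted over the list alone, with CCL2 at 4.04 ± 0.27 and CXCL8 at 3.71 ± 0.26. Collagen and adhesion genes were higher (median 0.53, adjusted p = 0.626 with an estimated correlation), where 18 of 29 passed upward and 5 downward over all genes and adjusted over the list alone, with FN1 at 4.79 ± 0.18 and CDH2 at 4.85 ± 0.11. Genes repressed by the Ewing fusion were higher too (median 0.60, adjusted p = 0.653 with an estimated correlation), with 11 of 22 upward and 3 downward, 11 and 4 adjusted over the list alone. Stress-response genes (median 0.53, adjusted p = 0.653 with an estimated correlation) had 10 of 19 upward and 1 downward, 13 and 1 adjusted over the list alone. Bone resorption signals (median 0.32, adjusted p = 0.833 with an estimated correlation) had 6 of 16 upward and 2 downward over all genes and adjusted over the list alone.

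Ribosomal protein genes were lower in A673 (median -0.46, adjusted p = 0.769 with an estimated correlation), led by RPS6 (-1.28 ± 0.11), with 10 of 17 downward and 0 upward, 14 and 1 adjusted over the list alone. Cholesterol genes were lower (median -0.41, adjusted p = 0.833 with an estimated correlation), led by HMGCS1 (-1.92 ± 0.11), with 7 of 15 downward and 2 upward, 10 and 2 adjusted over the list alone. Of the study's genes DKK2 was higher in A673 (1.02 ± 0.14) and so was JAG1 (1.21 ± 0.11), while CXCR4 (-2.64 ± 0.14), LEF1 (-1.34 ± 0.14) and ITM2A (-0.83 ± 0.14) were lower. The interferon list was higher in A673 (median 1.41, 15 of 23 passed, 19 adjusted over the list alone; adjusted p = 0.842 with an estimated correlation). Its median difference was 2.77 in the control arrays, 1.5 in the siITM2A arrays and -0.04 in the siDKK2 arrays. The 3 arrays of a line carried different siRNAs, so this comparison describes these arrays of the lines. The cholesterol call was lost without either siDKK2 array (median -0.24) and the bone resorption call without either control array (0.17). The interferon median was 0.93 without either control array and 2.21 without either siDKK2 array, and the chemokine median 0.36 without either control array.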

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

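Each of the following values was singled out because the cell lines moved at least 2-fold in opposite directions under the same siRNA comparison. The difference between the lines was not tested, since each line had 1 array per siRNA, and no test of an explanation was chosen here. THUMPD3-AS1, an antisense transcript, differed between siDKK2 and control by 1.49 in A673 and -1.96 in SK-N-MC. Between siDKK2 and siITM2A the same transcript differed by 1.78 in A673 and -1.12 in SK-N-MC. FAM27B differed between siITM2A and control by -1.0 in A673 and 1.08 in SK-N-MC. Both were dim, with means over the 6 arrays of 3.02 for THUMPD3-AS1 and 3.60 for FAM27B against a median of 4.04 over all genes.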

How the results depend on the processing

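The fit of every probe set, named or not, and the counts and correlations without the interferon list were chosen after the data were seen; the other settings were planned. The counts of changed genes (2 for siDKK2 against control, 2 for siITM2A against control, 3 for siDKK2 against siITM2A) were small, and the cause of their shifts was not tested. Without the line term they were 0, 0 and 0 (limma, 322, 230 and 272 at an unadjusted p under 0.05), and over every probe set 0, 0 and 0 (limma, 2443, 1867 and 2153). Most probe sets that the latter fit adds are not listed in the annotation used here, so they may not measure genes. The level filter gave 6 for siDKK2 against siITM2A, and the intensity trend gave 7 for siDKK2 against control and 16 for siDKK2 against siITM2A. With only the 4 arrays compared, siDKK2 against control gave 0 (limma, 1433 at an unadjusted p under 0.05) and siDKK2 against siITM2A 18. Leaving out 1 array gave 0 to 60, 0 to 4 and 1 to 50; each such fit had 1 residual degree of freedom, and the lone array was assumed to vary like the others. The highest counts, 60 and 50, came without the SK-N-MC siDKK2 array. DKK2 passed with an intensity trend for siDKK2 against control (adjusted p = 0.0254) and siDKK2 against siITM2A (0.00659), and in the latter under the level filter (0.0437), with TMEM87B and FERMT2; IFI44 with siDKK2 passed with the trend (0.0428). Without the line term the adjusted p of each was 1.00. IRF9 with siDKK2 passed under the level filter (adjusted p = 0.0221), an intensity trend (0.0165), robust moderation (0.0490) and median centring (0.0272), and its adjusted p ranged from 0.00463 without the SK-N-MC siDKK2 array to 1.00 without the line term. Quantile normalization gave 2, 2 and 3 genes, and no siRNA comparison moved the median of all genes by more than 0.043. The cell line count lay between 3729 and 5636 over all settings, against 5256. Called lists numbered 3, 3, 3 and 10 (line comparison last). They were 0 in each of the 4 comparisons with an estimated correlation, and 0, 0 and 0 by fry for the siRNA comparisons. The level filter gave 7 for siITM2A against control, and leaving out 1 array gave 1 to 5, 1 to 6 and 1 to 10. The interferon list's median with siITM2A reversed to 0.13 without the A673 control array and lay between -1.39 and 0.13 over the arrays left out. Under the level filter the bone resorption call between the lines was lost though its median was 0.70 against 0.32, and the cholesterol calls of siDKK2 against control and of the lines were lost at unchanged medians (-0.175 and -0.41). At 1.5-fold the genes shifted in both lines numbered 88, 47 and 90, against 13, 2 and 10 at 2-fold, the lower bar admitting more genes. Without the interferon list there were 4 for siDKK2 against control and 6 for siDKK2 against siITM2A. The correlation between lines was 0.295 for siDKK2 and 0.184 for siITM2A under the level filter. For siDKK2 in A673 with siITM2A in SK-N-MC it was 0.0576 under that filter, 0.0354 after quantile normalization and 0.0101 without the interferon list. Signal over background could not be measured, so which dim genes were detected is unknown.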

Other observations

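Tests of the interferon pattern, the comparison with siITM2A in the count pattern, and both explanations that rest on the oligonucleotide were chosen after the results were seen; the centring test and the splits of the arrays were planned, and the further interferon set was written after the fixed list's values were seen but before its own.

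Several genes of the fixed lists differed in the same direction in both lines with siDKK2 and passed when adjusted over their list alone, though not over all genes, where the adjusted p of those named in this paragraph lay between 0.220 for EGR1 and 0.378 for LCP1. Among Wnt receptors, FZD6 differed by -0.52 in A673 and -0.63 in SK-N-MC and FZD8 by 0.66 and 0.51, while the Wnt target gene SP5 differed by 0.44 and 0.55. The immediate early gene EGR1 differed by -1.27 and -0.64 and JUN by -0.63 and -0.48. Of the 19 measured immediate early genes 4 were higher and 5 lower in both lines, and the list was not called (camera, adjusted p = 0.575). JUN is also a member of the Wnt target list and passed there too, and 5 genes of that list were higher and 6 lower in both lines. The integrin gene ITGAV differed by -0.61 and -0.86, the smooth muscle actin gene ACTA2 by -0.84 and -0.62, and CHAC1 by -0.79 and -0.48. DICER1, the nuclease that makes microRNAs, differed by -0.65 and -1.05 with siDKK2, and by -0.37 and -0.84 with siITM2A. These DICER1 differences share the control arrays, so they are not separate results. Of 13 markers of blood cells, the macrophage marker CD68 differed by -1.31 and -0.38 and the leukocyte actin-bundling gene LCP1 by -0.53 and -0.44, alongside the lower interferon genes.

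Among 13837 probe sets without a name of their own, 17 were at least 2-fold lower and 19 higher with siDKK2 than with control in both lines, and 43 moved in opposite directions. The counts were 24 lower, 14 higher and 34 opposite for siITM2A against control, and 17, 16 and 21 for siDKK2 against siITM2A.

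Lower interferon genes with siDKK2 were weighed first. A shift that depends on signal level was argued against, because the lowest median of 10000 level-matched random lists was -0.25 in SK-N-MC, where the list stood at -0.79, and -0.41 in A673, where it stood at -3.07. Interferon genes raised in the control arrays alone were argued against as the whole cause, because siDKK2 stood below siITM2A as well, by -0.49 in SK-N-MC (lowest random median -0.23) and -1.91 in A673 (-0.33). Every array carried an siRNA, so genes raised in both the control and the siITM2A arrays could not be told apart from genes lowered by siDKK2. The design held 1 siRNA against DKK2, so loss of DKK2 and an effect of that oligonucleotide unrelated to DKK2 cannot be told apart. A further set of interferon-induced genes was lower too, with 30 of 38 lower in both lines and medians of -1.49 in A673 and -0.32 in SK-N-MC. These medians lay below every level-matched random set (-0.25 and -0.19), as a pattern wider than the fixed list would give. Random sets were drawn gene by gene, while interferon genes vary together, so the random range overstates the evidence. Against siITM2A the further set's SK-N-MC median of -0.13 lay inside the random range (lowest -0.17).

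With siDKK2 more named genes were lower than higher in both lines, 13 against 0 at 2-fold. Of the probe sets without a name of their own 17 were lower, 19 higher and 43 opposite, so they showed no leading direction. The annotation used here does not say what most of them measure, so they do not speak to the direction of gene changes. Without the interferon list 4 named genes were lower and 0 higher at 2-fold, and 64 lower and 11 higher at 1.5-fold. Only the listed genes were left out. The 1.5-fold count still holds genes of the further interferon set, such as IFIT5 (-2.28 in A673 and -0.86 in SK-N-MC) and BST2 (-2.87 and -0.80). The excess of lower genes thus overlaps with the interferon pattern and is not separate from it. An array-wide shift was argued against, since 61 named genes were lower and 13 higher by 1.5-fold after each array was centred on its median. Control arrays standing high were argued against as the whole cause, since 65 were lower and 25 higher against siITM2A. That comparison cannot speak to genes standing high in the control and siITM2A arrays alike. Off-target repression by the siDKK2 oligonucleotide may account for some of the genes and cannot be told apart from loss of DKK2, because the design held 1 siRNA against DKK2 and its sequence was not used here. Loss of DKK2 itself, the difference the design names, stays open and was not tested.

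Of the 10 splits of the 6 arrays into groups of 3, with siRNA as a block, 1, the real one, gave 5256 genes, and the highest of the others gave 0 (limma). Of these splits 4, the real one included, part the arrays of every siRNA; the other 6 put both arrays of a siRNA on 1 side and do not keep to the block. The splits were too few for a share under 0.05.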
